A study of Arabidopsis thaliana with 17 samples.

How the data were processed

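RNA was measured in leaves of Arabidopsis thaliana plants of the wild type (WT, accession Col-0) and of 2 lines, OE1 and OE2, that overexpress a bZIP transcription factor of the tea plant Camellia sinensis. Per the labels' protocols, plants spent 2 weeks on medium and were then moved to soil, under 10 h of light at 100 µmol per m2 and s and 14 h of dark, at 22 °C by day and 18 °C by night. At an age of 30 days they were kept for 4 days at 4 °C or at 22 °C, and each replicate came from 1 plant. From each plant, 0.2 µg of RNA was labelled with Cy3 and hybridised to 1 one-colour Agilent array. The 17 arrays form 6 groups of 3, except OE2 at 22 °C with 2, because a sample of that group had poor RNA according to the series description.

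The deposited scanner files give the intensity of each spot as Agilent Feature Extraction 10.7.1.1 wrote it, with background-subtracted and detrended processed signals and no scaling between arrays, per the file headers. The value table deposited by the authors holds log2 values for 43663 probes. All columns hold the same distribution, so it had been quantile-normalised between arrays, with column medians of 8.139 to 8.14. Its values correlated with the log2 processed signals at 0.9992 to 0.9999 within each array. Whether other steps preceded that table is not given in the sources used here. The table served as an alternative only.

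Each array holds 45220 spots, of which 1417 are controls, and 43603 probes for plant transcripts. The log2 processed signal was scaled by subtracting the array's 75th percentile. The scanner's marks for uneven or outlying spots removed 463 values, between 16 and 60 spots per array, and no spot was saturated. A probe was tested if its signal was well above background, by the scanner's own mark, on every array of at least 1 group. This left 33151 probes. Probes were named through the table of reference genes for assembly TAIR10.1, used only for names and not for positions. In this way, 36409 probes were assigned to 26435 genes, 34358 of them through an accession, 1880 through a locus code and 171 through other accessions, and 7194 had no gene. For a gene with several probes, the brightest stood for the gene, which left 21124 genes. The probe for the tea transcript is not on the array, so the overexpression itself could not be checked.

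The number of arrays limits the precision, and 69.9 to 75.6% of the spots of an array were well above background. Where no array of a group was above background for a gene, a fold against that group is only a bound: the dim values were raised to the lowest signal that counted as above background on their array, and the change is given as at least that many fold. For the mean of both lines, the interaction, and MYB57 and ORA47 in OE1, this was done for each dim array of the lower side. Dim arrays of the brighter side kept their values. No fold is given where both sides were dim, or where the group that would have to be lowered was.

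Groups were compared in R 4.3.3 with limma 3.58.1 (statmod 1.5.0, and data.table at version 1.17.8). A linear model with 6 group means over all 17 arrays gave log2 differences and moderated tests with empirical Bayes variances. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. The comparisons were the cold response in each genotype, each line against WT at each temperature, the mean of both lines against WT at each temperature, the line against the other line, and the difference between the cold response of the lines and that of WT (an interaction contrast). The p-values measure the spread between single plants.

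The 18 gene lists covered cold signalling regulators, cold-regulated effectors, ABA metabolism and signalling, ABA- and drought-responsive genes, sugar and osmolyte metabolism, photosynthesis, flavonoid and anthocyanin synthesis, the circadian clock, salicylic acid and pathogen defence, jasmonate synthesis and response, heat shock and chaperones, leaf senescence, Arabidopsis bZIP factors, and markers of root, flower and flowering time, guard cells, vasculature, and epidermis with trichomes. They were written from general knowledge, not from these samples. Lists were tested against all other genes with camera in limma, at a preset inter-gene correlation of 0.01, and again with an estimated correlation. fry, which tests a list against no change and not against other genes, was run beside it. Adjustment was over the 18 lists of a comparison. A list's direction is that of its median unless stated.

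The genes named were set by a rule. It takes the 6 largest rises and the 6 largest falls among called genes with a symbol whose arrays do not overlap between the groups, up to 2 called members of each list with the smallest p or else 1 member, 13 cold and ABA genes in every case (CBF1, CBF2, CBF3, ICE1, COR15A, COR15B, COR47, RD29A, RD29B, KIN1, KIN2, ABI5 and RAB18), and 4 rises and 4 falls between the lines and among the calls shared by both. For the interaction the arrays were not required to separate. Any gene outside the rule is marked as such. Samples, comparisons, gene lists, the naming rule and the other settings to try were fixed before the data were examined. Lists of nitrate-induced, floral organ and pollen genes, and 4 alternatives that use them or leave out arrays, were added after seeing the data.

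Slides and scan days are recorded in the scanner files and were treated as possible batches. The 22 °C arrays filled 2 slides scanned on 1 day and the 4 °C arrays filled 3 slides scanned on the other day, so temperature cannot be told apart from slide and scan day. WT and OE1 shared 1 slide at each temperature, and comparisons that allow it were repeated with the slide as a fixed block, the others with a correlation within slides. Under the fixed block the lines against WT at 22 °C rest on 1 line plant, OE1 replicate 1, and OE1 against WT at 4 °C on 1 WT plant, replicate 3.

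The other settings chosen then were quantile normalisation, background correction by normexp with an offset of 50 followed by quantile normalisation, the authors' table, no filter and a strict filter on dim probes (above background on all arrays), a 75th percentile over bright probes only, the mean of a gene's probes, a trended and robust variance, array weights, only the arrays compared, replicate number as a block, slide as a block, a threshold of 2-fold, and leaving out each array in turn. Leaving out an OE2 array at 22 °C left that group 1 plant, and leaving out WT replicates 2 and 3 and OE1 replicate 3 at 4 °C left WT 1 cold plant. Such a lone plant is assumed to vary like the other groups. Overlap between comparisons that share the WT arrays was set beside 100 simulations of unchanged groups, and up to 100 other splits of the arrays were counted. The 3 WT arrays are too few to split.

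The tests were checked on simulated data built on 20948 genes, with 100 genes changed at each size. For the cold response of WT, 56% of changes of 1 on the log2 scale and 82% of changes of 2 were recovered, with 13 false calls. For both lines against WT these were 57% and 91% with 15 false calls at 22 °C and 57% and 90% with 8 at 4 °C. For the interaction they were 35% and 78% with 9. Splits of the real arrays called up to 8614 genes at 4 °C and 3485 for the interaction, so these false calls are no error rate here.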

Results

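Transcripts of 21124 genes were measured in leaves of single Arabidopsis plants. WT plants and plants of 2 lines that overexpress a bZIP transcription factor of tea, OE1 and OE2, had been kept for 4 days at 22 °C or at 4 °C. There were 3 arrays per group, except 2 for OE2 at 22 °C, and 17 in all. The series title presents the factor as a negative regulator of freezing tolerance, and the comparisons ask which transcripts respond to cold, which differ in the lines, and whether the lines respond to cold differently. Freezing tolerance itself was not part of the array data, and the tea transcript has no probe. The 75th percentile of the processed signal ran from 1143.5 to 4066.9 intensity units between arrays. Values are log2 differences from limma with their standard error (SE), and the adjusted p is over all genes tested.

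The arrays separated first by temperature. Among the 4 °C arrays, WT replicate 1 stood apart from the other WT plants. On the first principal component of these 9 arrays, which held 51.6% of the variance, WT replicates 2 and 3 lay at -100.7 and -93.2, WT replicate 1 at 31.9, and the OE2 arrays between 36.5 and 40.5. OE1 replicates 1 and 2 lay at 33.9 and 37.5 and OE1 replicate 3 at -23. Correlations across genes within the WT group at 4 °C ran from 0.9458 to 0.9828, against 0.9845 to 0.9885 within OE2 at 4 °C, and genes are not independent replicates. Among the 22 °C arrays, the first component held 31.9% of the variance. It placed WT at 34.7 to 37.5, OE2 at -57.9 and -54.5, and OE1 between 25.1 and -24.6.

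**Figure D1:**
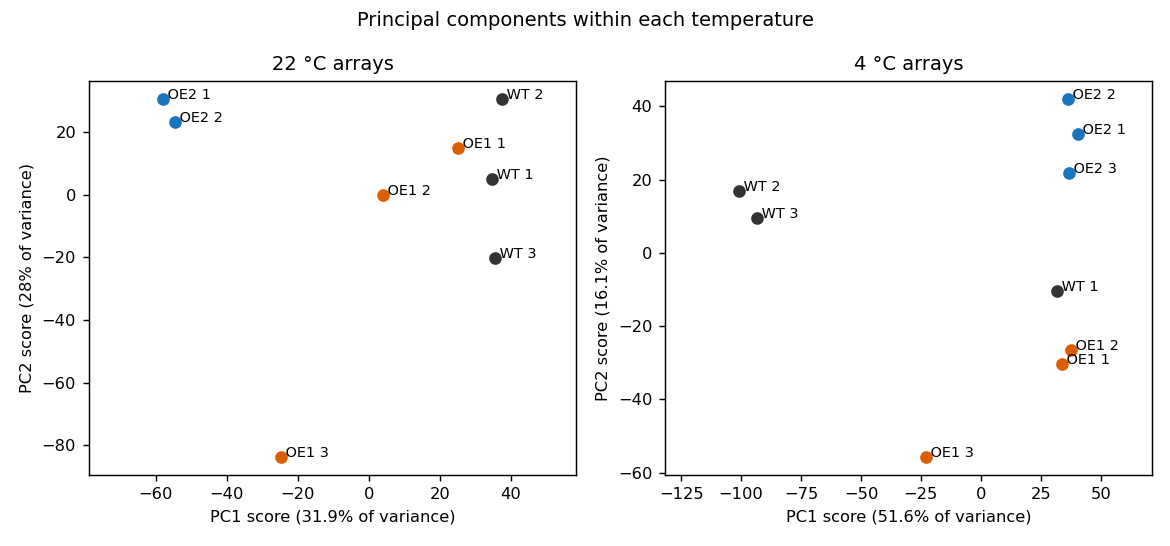
Principal components 1 and 2 of the 22 °C arrays (31.9 and 28% of variance) and of the 4 °C arrays (51.6 and 16.1%), computed separately, 1 point per plant, coloured by genotype. At 4 °C, WT replicate 1 (31.9 on component 1) lies near OE1 replicates 1 and 2 and the OE2 arrays and far from WT replicates 2 and 3 (-100.7 and -93.2).

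In WT leaves, 4 days at 4 °C changed cold-protection, flavonoid, photosynthesis and heat shock genes together. The galactinol synthase GOLS3 (AT1G09350), which makes the precursor of raffinose sugars, rose by 9.11 ± 0.415 (SE, n = 3 against 3, adjusted p = 3.02e-09). COR27 (AT5G42900), a cold-induced regulator tied to the clock, rose by 7.65 ± 0.435, the dehydrin LTI30 (AT3G50970) by 7.41 ± 0.45, and the starch-debranching enzyme ISA3 (AT4G09020) by 7.26 ± 0.282. The receptor-like protein gene RLP33 (AT3G05660) was at least 74.5-fold higher and the flavonol glycosyltransferase gene UGT78D3 (AT5G17030) at least 66.2-fold higher, since no WT array at 22 °C was above background for them. The small heat shock genes HSP17.6A (AT5G12030), HSP17.4 (AT3G46230) and HSP23.6 (AT4G25200) were at least 284.3-, 261.4- and 146.5-fold lower. The polygalacturonase gene PGA4 (AT1G02790) was at least 231.1-fold lower. The asparagine synthetase ASN1 (AT3G47340), known for its induction in the dark, fell by 9.79 ± 0.729 and the peroxidase PER64 (AT5G42180) fell by 9.48 ± 0.804, and each was above background on 1 of 3 cold arrays.

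Cold signalling and its targets rose in WT. Of 22 cold signalling regulators 12 rose and 3 fell, over all genes and adjusted over the list alone, with a median of 0.465 (adjusted p = 0.0224, adjusted p = 0.376 with an estimated correlation). The CBF factors, which switch on freezing-protection genes, were among the risers: CBF1 (AT4G25490) was at least 13.6-fold higher, CBF2, above background on 2 of 3 arrays at 22 °C, rose by 5.32 ± 0.536 and CBF3 by 4.26 ± 0.356. The zinc finger gene CZF1 rose by 2.29 ± 0.179, and ICE1, which acts upstream of the CBF genes, by 0.40 ± 0.123 (adjusted p = 0.0132). Of 30 cold-regulated effectors 23 rose and 4 fell, also adjusted over the list alone, with a median of 2.64 (adjusted p = 2.88e-08, or 0.222 with an estimated correlation). Among them the chloroplast-protecting proteins COR15A and COR15B rose by 5.72 ± 0.333 and 6.54 ± 0.303, and the stress proteins RD29A by 5.89 ± 0.264, KIN1 by 2.94 ± 0.262, KIN2 by 2.2 ± 0.275 and COR47 by 1.49 ± 0.156. The RNA-binding protein GRP7 rose by 4.99 ± 0.178 and the light-stress protein ELIP1 by 5.12 ± 0.221.

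**Figure D2:**
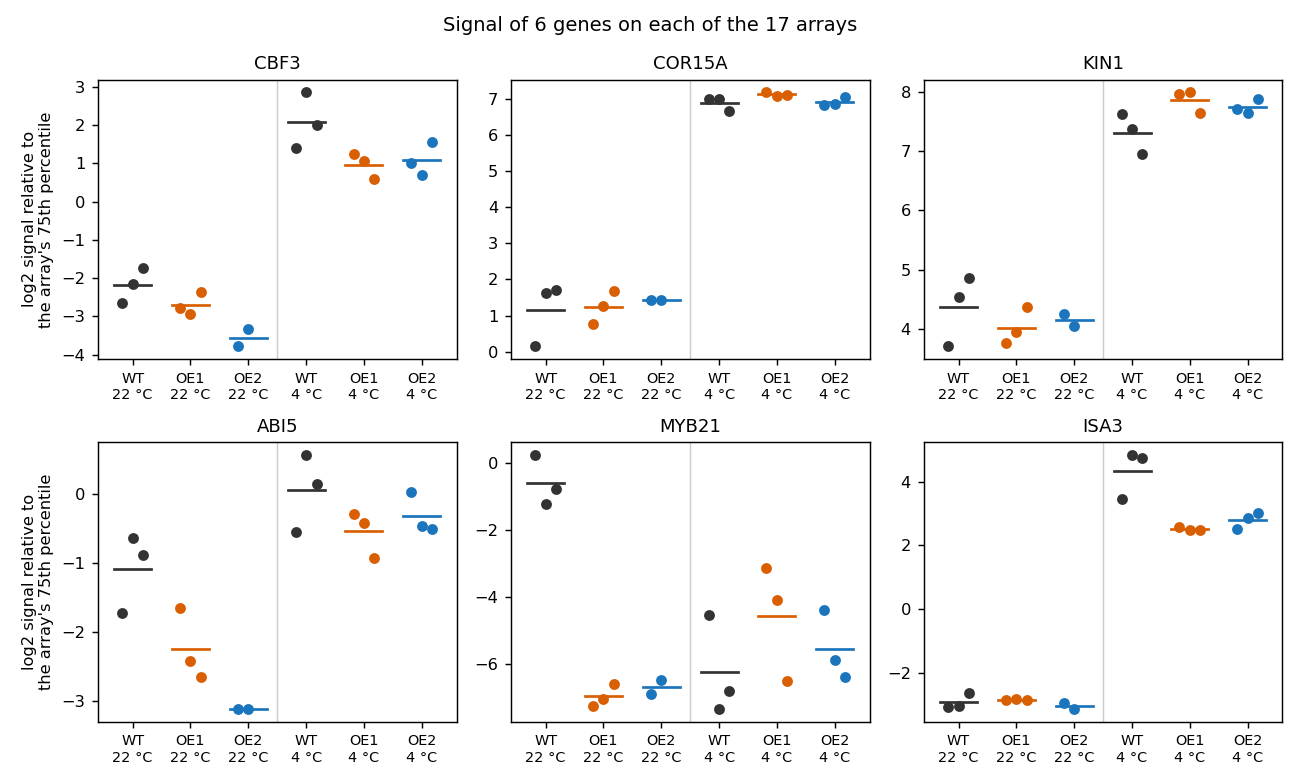
Log2 signal relative to the array's 75th percentile for CBF3, COR15A, KIN1, ABI5, MYB21 and ISA3, 1 point per plant with the group mean as a line, for 3 genotypes at both temperatures. COR15A and ISA3 are higher at 4 °C in every genotype, and MYB21 is well above background at 22 °C in WT and in none of the 5 line plants.

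Flavonoid synthesis was the list with the largest rise in WT. Of 24 genes 21 rose and 1 fell, also adjusted over the list alone, with a median of 4.11 (adjusted p = 3.13e-10, or 0.222 with an estimated correlation). Chalcone synthase, TT4, which starts the pathway, rose by 5.03 ± 0.199 and the flavonoid hydroxylase TT7 by 6.92 ± 0.317. Of 23 clock genes 15 rose and 7 fell, also adjusted over the list alone, with a median of 1.58 (adjusted p = 0.00777, or 0.376 with an estimated correlation). The evening component TOC1 rose by 4.38 ± 0.151 and COR28, a relative of COR27, by 6.95 ± 0.35. Of 20 sugar and osmolyte genes 9 rose, among them the starch-degrading amylase BAM3 by 2.74 ± 0.121, and 5 fell, also adjusted over the list alone, and the list was not called (median 0.584, or 0.332 with a dim member at its bound, adjusted p = 0.117).

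Photosynthesis, heat shock, jasmonate, flower, vascular and ABA metabolism lists fell in WT. Of 30 photosynthesis genes 28 fell and 1 rose, and adjusted over the list alone 29 fell (median -1.74, adjusted p = 1.07e-10, or 0.357 with an estimated correlation). The antenna proteins LHCB4.2 and LHCB2.1 fell by 4.01 ± 0.216 and 3.58 ± 0.226. Of 15 heat shock and chaperone genes 11 fell and 2 rose, and adjusted over the list alone 12 fell, with a median of -5.82, or -5.39 with 4 dim members at their bounds (adjusted p = 1.77e-05, or 0.222 with an estimated correlation), and HSP90.1 fell by 6.85 ± 0.285. Of 29 jasmonate genes 22 fell and 0 rose, and adjusted over the list alone 23 fell, with a median of -1.93 (adjusted p = 1.77e-05, or 0.287 with an estimated correlation). The thionin THI2.1 was at least 105.4-fold lower and the jasmonate regulator MYC2 fell by 2.57 ± 0.222. Of 12 flower and flowering-time genes 8 fell, among them AGL24 by 1.80 ± 0.133 and SOC1 by 1.22 ± 0.149, 9 adjusted over the list alone, with a median of -1.75 (adjusted p = 0.00777, adjusted p = 0.376 with an estimated correlation). Of 12 vascular markers 7 fell and 1 rose, also adjusted over the list alone, with a median of -1.42 (adjusted p = 0.00777, adjusted p = 0.357 with an estimated correlation), and the xylem genes XCP1 and IRX1 fell by 3.11 ± 0.246 and fell by 4.05 ± 0.331. Of 36 genes of ABA metabolism and signalling 19 fell and 7 rose, also adjusted over the list alone, with a median of -0.668 (adjusted p = 0.0306, or 0.376 with an estimated correlation). The phosphatase HAI1, which restrains ABA signalling, fell by 4.02 ± 0.362 and the bZIP factor ABF1 rose by 2.81 ± 0.205.

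The other lists were not called in WT at 4 °C. Of 20 ABA- and drought-responsive genes 3 rose and 7 fell, also adjusted over the list alone (median -0.343, adjusted p = 0.549). Alcohol dehydrogenase ADH1 rose by 5.63 ± 0.349 and the seed protein gene EM1 was at least 9-fold lower. RD29B at 0.36 ± 0.409 (adjusted p = 0.472) and RAB18 at 0.60 ± 0.499 (adjusted p = 0.323) did not pass, and ABI5, a bZIP factor of the ABA pathway, rose by 1.13 ± 0.342 (adjusted p = 0.012). Of 21 salicylic acid and defence genes 9 rose and 2 fell, also adjusted over the list alone (median 0.792, adjusted p = 0.106), and the defence proteins PR5 and NUDT6 rose by 4.44 ± 0.42 and 4.63 ± 0.532. Of 43 Arabidopsis bZIP factors 11 rose and 19 fell, also adjusted over the list alone (median -0.347, adjusted p = 0.25), and GBF1 fell by 1.65 ± 0.13. Of 11 senescence genes 1 rose and 2 fell, and adjusted over the list alone 1 rose and 1 fell, with a median of 0.082, a mean of -0.657 and a test toward lower values (adjusted p = 0.656). In that list DIN10, a sugar-starvation gene, fell by 4.67 ± 0.94 and NYC1, a chlorophyll-breakdown enzyme, rose by 0.44 ± 0.128. Among markers of other cell types, the root list (median -0.634, adjusted p = 0.355), guard cell list (median 0.441, adjusted p = 0.355) and epidermis list (median -0.375, adjusted p = 0.285) did not pass. In these, 1, 4 and 2 genes rose and 3, 1 and 4 fell, and adjusted over the list alone 2, 4 and 2 rose and 3, 1 and 5 fell. The root markers PRP3, at least 2.8-fold lower, and SCR, lower by 1.02 ± 0.14 on the log2 scale, the guard cell genes MUTE, which rose by 1.42 ± 0.179, and HT1, which fell by 0.98 ± 0.217, and the trichome genes TRY, which fell by 3.36 ± 0.178, and GL3, above background on 1 of 3 arrays at 22 °C, which rose by 3.24 ± 0.214, were called.

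In all, limma called 12175 of 21124 genes in the cold response of WT, 5975 higher and 6200 lower (49.1% higher, against 57.2% from 7026 and 5266 after quantile normalisation and 57.3% from 7028 and 5247 in the authors' table). Of the calls, 2751 rose and 3894 fell by at least 2-fold. Quantile normalisation moved the median over all genes from -0.002 to 0.123 and the authors' table moved it to 0.125, so changes of that size depend on the scaling. Of 55 named calls 53 held with each array left out. ICE1 had an adjusted p of 0.0531 without WT replicate 3 at 22 °C (0.00418 to 0.196 over all alternatives). ABI5 had 0.0626 without WT replicate 1 at 22 °C and 0.0566 without WT replicate 2 at 4 °C (0.00279 to 0.307). The lists of ABA metabolism and of cold regulators had medians of -0.544 and 0.798 and an adjusted p of 0.0723 and 0.0582 without WT replicate 1 at 4 °C (0.000126 to 0.376 for both).

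The lines showed the same main cold-induced genes as WT. CBF3 rose by 3.66 ± 0.356 in OE1 (n = 3 against 3) and by 4.65 ± 0.398 in OE2 (n = 3 against 2), COR15A by 5.87 ± 0.333 and 5.50 ± 0.372, and ISA3 by 5.35 ± 0.282 and 5.85 ± 0.315. TT4 rose by 4.64 and 3.94, GOLS3 by 7.07 and 8.63, COR15B by 7.77 and 7.24, KIN1 by 3.84 and 3.59, and COR47 by 1.89 and 1.92. In OE1 and OE2, 22 and 24 of the 30 cold-regulated effectors rose, 21 and 21 of the 24 flavonoid genes rose, and 24 and 28 of the 30 photosynthesis genes fell. limma called 12535 genes in OE1, 6519 higher and 6016 lower, and 11941 in OE2, 5971 higher and 5970 lower. Of these 4135 were higher and 4069 lower in all 3 genotypes, and 53 were called in opposite directions in OE1 and OE2. Fold changes correlated across genes at 0.888 between WT and OE1, 0.81 between WT and OE2 and 0.866 between the lines, and genes are not independent replicates. Whether the responses differ was tested directly, as given with the interaction.

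**Figure D3:**
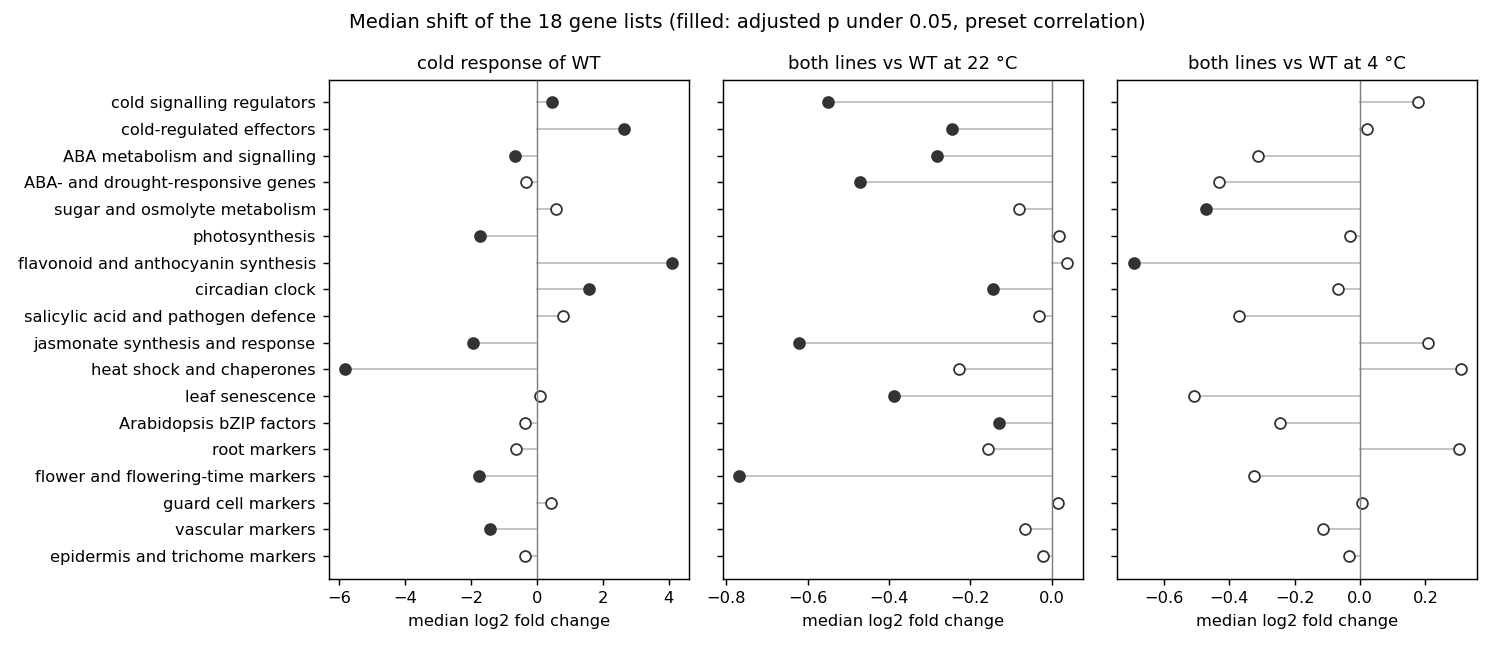
Median log2 difference of 18 gene lists (x axis) in the cold response of WT, in both lines against WT at 22 °C and in both lines against WT at 4 °C, with filled points where the adjusted p of camera at the preset correlation was under 0.05. Flavonoid genes (4.11) and cold-regulated effectors (2.64) lie highest in the cold response of WT, and jasmonate genes (-0.62) lie below 0 in the lines at 22 °C.

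At 22 °C, before any cold, the transcription factors MYB21, MYB57 and ORA47 were lower in both lines than in WT. MYB21 (AT3G27810), a jasmonate-responsive factor of stamen and petal growth, was at least 52.8-fold lower (adjusted p = 0.00461, n = 5 line plants against 3 WT plants), and was above background in 3 of 3 WT plants and in none of the line plants. Its relative MYB57 (AT3G01530) was at least 20.4-fold lower (adjusted p = 0.00921) and was above background in 1 line plant, of OE1. ORA47 (AT1G74930), an early jasmonate-induced factor of jasmonate synthesis, was at least 7.8-fold lower (adjusted p = 0.000203), also above background in 1 OE1 plant alone. The protease gene CEP2 fell by 4.75 ± 0.613 (adjusted p = 0.00711, 1 of 2 OE2 plants at background), the glutathione transferase gene GSTU2, above background in 1 OE1 plant alone, was at least 6.4-fold lower (adjusted p = 0.0222), and the cellulase-family gene GH9B15 (AT4G23560) was at least 4.8-fold lower (adjusted p = 0.000203). Fewer genes were higher: the cellulase-family gene GH9B6 and the purine permease gene PUP17 were at least 1.7-fold higher (adjusted p = 0.0409 and 0.0496). The protease gene DEG4 passed (adjusted p = 0.0232) but was dim in all but 1 plant, so no fold is given.

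Jasmonate genes as a group fell in the lines at 22 °C. Of 29 members 28 lay below 0, 1 fell, and adjusted over the list alone 8 fell, with a median of -0.62 (adjusted p = 2.15e-13, or 0.0916 with an estimated correlation). The defensin PDF1.2B fell by 1.84 ± 0.284 (adjusted p = 0.0136). The NAC factors NAC055 and NAC019, which act in jasmonate and drought responses, fell by 1.69 ± 0.279 and 1.94 ± 0.343 (adjusted p = 0.0217 and 0.0295) in the ABA- and drought-responsive list. Of its 20 members 2 fell, 5 adjusted over the list alone, with a median of -0.47 (adjusted p = 9.76e-07, or 0.124 with an estimated correlation). In the list of ABA metabolism and signalling ABI5, a bZIP factor of ABA signalling, fell by 1.59 ± 0.308 (adjusted p = 0.0409), with overlapping arrays. Of its 36 genes 1 fell, 2 adjusted over the list alone, with a median of -0.282 (adjusted p = 7.29e-06, adjusted p = 0.0944 with an estimated correlation). ORE1, a NAC factor that promotes senescence, fell by 1.25 ± 0.252 (adjusted p = 0.0496). Of 11 senescence genes 1 fell, 2 adjusted over the list alone, with a median of -0.388 (adjusted p = 4.48e-05, adjusted p = 0.0916 with an estimated correlation). Of 43 bZIP factors ABI5 alone fell, also adjusted over the list alone, with a median of -0.13 (adjusted p = 0.000522, adjusted p = 0.292 with an estimated correlation).

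The cold lists were lower as groups at 22 °C while none of their single genes passed over all genes. Of 22 cold signalling regulators 0 changed in limma, and adjusted over the list alone 10 fell, with a median of -0.549 (adjusted p = 1.25e-08, adjusted p = 0.0916 with an estimated correlation). The zinc finger gene AZF2 stood at -1.01 (adjusted p = 0.0561), CBF3 at -0.94 ± 0.321 (adjusted p = 0.306), and CBF2 at -0.97 ± 0.483 (adjusted p = 0.617), while CBF1 was at background in WT. Of 30 cold-regulated effectors 0 changed, and adjusted over the list alone 2 fell, with a median of -0.246 (adjusted p = 0.00437, adjusted p = 0.484 with an estimated correlation). COR15A stood at 0.17 ± 0.3 (adjusted p = 0.931), COR15B at -0.54 (0.632), COR47 at -0.28 (0.632), RD29A at 0.13 (0.934), RD29B at 0.71 (0.642), KIN1 at -0.28 (0.848), KIN2 at -0.31 (0.841), RAB18 at -0.46 (0.873), LTI30 at -1.56 (0.141) and ICE1 at 0.04 (0.962), and none passed. Over all genes, 1884 had an unadjusted p under the threshold. Of 23 clock genes 0 changed, 2 fell adjusted over the list alone, and the list had a median of -0.145 (adjusted p = 0.0243, adjusted p = 0.484 with an estimated correlation), with ELF3 at -0.57 (adjusted p = 0.122).

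The list of flower and flowering-time markers was lower in the lines at 22 °C, with single plants apart. Of 12 genes 0 changed in limma over all genes and 1 rose adjusted over the list alone, AGL24 at 0.43 among the highest (adjusted p = 0.18), while the list's median was -0.768 (adjusted p = 0.000531, adjusted p = 0.342 with an estimated correlation). A score of 7 floral organ genes, chosen after seeing the data and centred over all arrays, was 1.788 to 2.133 in WT plants, 1.975, 1.058 and -0.06 in OE1 plants, and 0.561 and 0.704 in OE2 plants. A score of 8 pollen genes was 2.984 to 4.461 in WT, 3.55, 3.038 and -1.333 in OE1, and -0.059 and -0.364 in OE2. With the floral score as a covariate 56 genes were called in place of 111. MYB21 (adjusted p = 0.0111) and ORA47 (0.00117) passed. PDF1.2B at -1.81 (0.0507, against -1.84), ABI5 at -1.43 (0.162, against -1.59), ORE1 at -1.11 (0.179, against -1.25), and GSTU2 (0.0884) and GH9B6 (0.146), each dim in a group, did not pass, over ranges of 7.65e-05 to 0.252 for MYB21 and 0.000729 to 1 for PDF1.2B among the alternatives. The lists not called were sugar (median -0.081, adjusted p = 0.316), photosynthesis (0.019, 0.513), flavonoid synthesis (0.037, 0.63), salicylic acid and defence (-0.032, 0.38), heat shock (-0.229, 0.63), and markers of root (-0.157, 0.543), guard cells (0.016, 0.909), vasculature (-0.066, 0.19) and epidermis (-0.021, 0.645). Their members with the smallest p, ERD5 at -1.39, LHCB4.3 at 0.27, 4CL3 at 0.66, GRX480 at -1.95, HSP21 at -1.83, PRP3 at -0.54, SLAC1 at -0.52, IRX3 at -0.53 and GL2 at -0.31, did not pass.

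**Figure D4:**
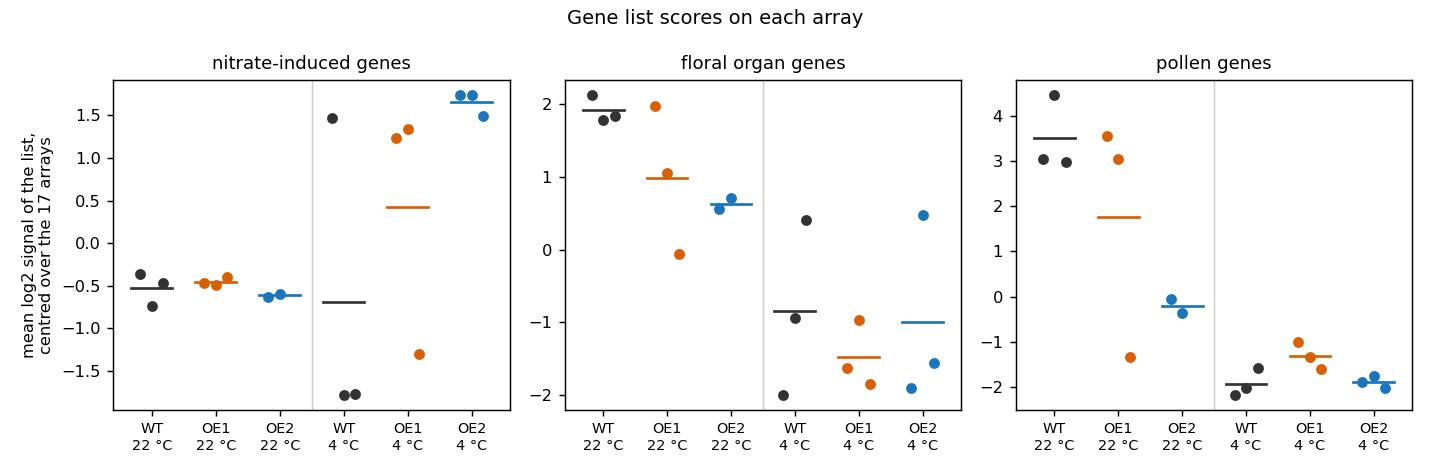
Mean log2 signal of nitrate-induced, floral organ and pollen genes per plant, centred over the 17 arrays, with group means as lines. At 22 °C the floral score is 1.788 to 2.133 in WT and 0.561 and 0.704 in OE2, and at 4 °C the nitrate score is 1.466 in WT replicate 1 and -1.779 and -1.77 in the other WT plants.

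limma called 111 genes in both lines against WT at 22 °C, 8 higher and 103 lower (7.2% higher), and the split was 47 higher and 123 lower (27.6%) after quantile normalisation and 47 and 120 (28.1%) in the authors' table. The count was 184 without WT replicate 1 and OE1 replicate 3 at 4 °C. With the slide as a block 11 genes were called, 7 higher and 4 lower. Each value of the lines against WT then passes through a single plant, OE1 replicate 1, the line plant on the slide of WT. ORA47 passed (adjusted p = 0.016), while MYB21 (0.252), GH9B15 (0.123), CEP2 (0.125) and MYB57 (0.795) did not. The median of the jasmonate list was -0.868 under this block and that of the flower list 0.136, values that 1 plant sets. Through that plant the salicylic acid (-0.882, 9.08e-07), vascular (-0.364, 5.84e-07), sugar (-0.344, 0.0126) and heat shock (0.41, 0.00111) lists gained a call and the clock list lost it (-0.083, 0.261). Left-out arrays moved the count to 69 and 22 (WT replicates 2 and 3 at 22 °C), 214 and 49 (OE1 replicates 1 and 2 at 22 °C), 29 (OE2 replicate 1 at 22 °C), 67 and 57 (OE1 replicates 1 and 2 at 4 °C), and 66 and 68 (OE2 replicates 2 and 3 at 4 °C). GH9B15, ORA47, MYB21 and CEP2 were the 4 of 14 named calls that held with each array left out.

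The other 10 named calls of this comparison were lost with single arrays left out. MYB57 was lost without WT replicate 3 at 22 °C (adjusted p = 0.0523, 0.000622 to 0.795 over all alternatives) and PDF1.2B without WT replicates 2 (0.0548) and 3 (0.0743). DEG4 was lost without WT replicates 2 (0.0804) and 3 (0.104), OE1 replicate 2 (0.0514) and OE2 replicate 1 (0.0997), with 0.00406 to 0.749 over all. GSTU2 was lost without WT replicates 1 (0.0767), 2 (0.0529) and 3 (0.0638) and OE2 replicate 1 (0.097), with 0.000423 to 1 over all. NAC055 was lost without WT replicates 2 (0.0786) and 3 (0.104), OE1 replicate 2 (0.051) and OE2 replicate 1 (0.097), with 0.00672 to 0.955 over all. NAC019 was lost without WT replicates 2 (0.115) and 3 (0.141), OE2 replicates 1 (0.11) and 2 (0.0631), and OE1 replicate 2 at 4 °C (0.0515), with 0.00969 to 1 over all. PUP17, GH9B6, ABI5 and ORE1 were lost without 14, 12, 12 and 14 of the 17 arrays, at adjusted p up to 0.21, 0.153, 0.181 and 0.209. Of the 14 calls, 10, 5 and 4 were kept without WT replicates 1, 2 and 3 at 22 °C, 13, 8 and 10 without those of OE1, 7 and 9 without those of OE2, and 9 to 14 without a 4 °C array. The list of cold-regulated effectors was lost without WT replicate 3 (median -0.092, adjusted p = 0.413), and the clock list without WT replicate 2 (0.295) and OE1 replicate 2 (0.06), with 1.06e-06 to 0.484 and 0.00365 to 0.484 over all.

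Each line alone showed the fall of MYB21, GH9B15 and ORA47 at 22 °C. In OE1 (n = 3 against 3) ORA47, above background in 1 plant, was at least 5.9-fold lower (adjusted p = 0.00735), and in OE2 (n = 2 against 3), where it was at background, it was at least 10.3-fold lower (0.000154). MYB21 was at least 48.2-fold lower in OE1 (0.0159) and 57.9-fold in OE2 (0.0079), and GH9B15 at least 4.4- and 5.3-fold (0.00349 and 0.000912). MYB57 was at least 17.5-fold lower in OE1 (0.0363), with 1 plant above background, and was at least 23.8-fold lower in OE2 (0.0112). The jasmonate list fell in both, with medians of -0.558 (adjusted p = 5.7e-09, adjusted p = 0.106 with an estimated correlation) and -0.86 (adjusted p = 6.44e-11, adjusted p = 0.155 with an estimated correlation). The salicylic acid list rose in OE1 (0.254, adjusted p = 0.0226, adjusted p = 0.547 with an estimated correlation) and fell in OE2 (-0.468, adjusted p = 0.00329, adjusted p = 0.468 with an estimated correlation). The mean log2 signal of this list was -2.29 to -1.37 in WT plants, -2.17, -1.78 and -0.35 in OE1 plants, and -2.72 and -2.57 in OE2 plants, so only OE1 replicate 3 lay above the WT plants. limma called 11 genes in OE1, 1 higher and 10 lower, and 325 in OE2, 32 higher and 293 lower (9.8% higher, against 26.1% from 103 and 291 after quantile normalisation and 26.9% from 105 and 286 in the authors' table). Of these, 10 were shared in direction, 1 higher and 9 lower. Independent lists would share 0.00152 higher and 0.139 lower, and 100 simulations of unchanged groups with the same WT arrays gave a median of 0 and at most 58. The covariance of fold changes was 0.14, against 0.071 in the simulations (0.001 to 0.213), and the correlation 0.51 against 0.523. Part of the shared calls may come from the common WT plants, which were not split.

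Left-out arrays moved these counts. The count for OE1 went to 29 and 5 without WT replicates 2 and 3 at 22 °C, to 51 without OE1 replicate 1 at 22 °C, and to 7 without OE2 replicate 2 at 4 °C. The count for OE2 went to 208, 213 and 144 without WT replicates 1, 2 and 3, to 47 and 145 without OE2 replicates 1 and 2 at 22 °C, to 669 without WT replicate 1 at 4 °C, and to 208 and 216 without OE1 replicates 1 and 2 at 4 °C. The shared count went to 27 and 4 without WT replicates 2 and 3, to 39 and 6 without OE1 replicates 1 and 2, and to 4 and 6 without OE2 replicates 1 and 2. With the slide as a block OE2 had 40 calls, 10 higher and 30 lower.

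At 4 °C, the lists of flavonoid synthesis and of sugar and osmolyte genes were lower in both lines than in WT, with medians of -0.693 and -0.471 (adjusted p = 4.49e-05 and 0.0358, adjusted p = 0.719 and 0.373 with an estimated correlation). Neither list of cold genes was called. ISA3, the starch-debranching enzyme, fell by 1.69 ± 0.244 (adjusted p = 0.0103, n = 6 line plants against 3 WT plants), the disproportionating enzyme DPE2 (AT2G40840), which uses maltose, by 1.22 ± 0.251 (0.0382), and the maltose exporter MEX1 by 0.92 ± 0.148 (0.0159). The epimerase UGE5 fell by 1.53 ± 0.207 (0.0103), the cytochrome P450 CYP71B24 by 1.68 ± 0.379 (0.0424) and the carboxylesterase CXE13 by 1.25 ± 0.28 (0.0423). The expansin gene EXPB1 passed (0.0286) with a bound of only 1-fold, above background in WT replicates 2 and 3 alone. The calcium-sensor kinase CIPK16 (AT2G25090) was higher by 2.37 ± 0.352 (0.0112), the vacuolar iron transporter VIT1 by 2.31 ± 0.579 (0.0475), the chaperone CLPB2 (AT4G14670) by 2.27 ± 0.361 (0.014), the oil body protein OLEO1 (AT4G25140) by 1.80 ± 0.372 (0.0382) and CRP4 by 1.76 ± 0.273 (0.012), and EXPB6 (AT1G65681) was at least 1.9-fold higher (0.0103), above background in 3 of 6 line plants. WT was above background on 1 of 3 arrays for CIPK16, CLPB2 and CRP4 and on 2 of 3 for VIT1 and UGE5.

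CBF3 was lower in the lines at 4 °C by 1.06 ± 0.309 on the log2 scale (adjusted p = 0.0497), with overlapping arrays, and a similar gap at 22 °C was not called. With single arrays left out, the CBF3 call held only without WT replicate 1 or OE1 replicate 3 at 4 °C. CBF1 at 0.29 ± 0.507 (0.691) and CBF2 at 0.10 ± 0.464 (0.882) did not pass. MYB15, a repressor of CBF genes, was higher by 1.53 ± 0.432 (0.0494, WT above background on 2 of 3 arrays). Of 22 cold regulators these 2 changed, 1 each way, with a list median of 0.176 (adjusted p = 0.678, or 0.938 with an estimated correlation). Of 30 cold-regulated effectors 2 rose and 2 fell, with a median of 0.02, a mean of -0.03 and a test toward lower values (adjusted p = 0.705, or 0.938 with an estimated correlation). The chloroplast membrane proteins COR413IM1 and COR413IM2 fell by 1.00 ± 0.222 (0.041) and 0.67 ± 0.154 (0.044). COR15A stood at 0.13 ± 0.288 (0.757), COR15B at 0.43 ± 0.262 (0.238), COR47 at 0.14 ± 0.135 (0.454), RD29A at 0.08 ± 0.229 (0.817), RD29B at -0.03 (0.965), KIN1 at 0.50 ± 0.227 (0.124), KIN2 at 0.48 ± 0.238 (0.151), RAB18 at -1.05 ± 0.432 (0.0968), ABI5 at -0.48 ± 0.296 (0.237) and ICE1 at 0.20 (0.173), and none passed. COR15A, COR47 and RD29A lay below 0 after quantile normalisation, after background correction and in the authors' table, and KIN1 in the last 2 of these. The ABA- and drought-responsive list had a median of -0.433 (adjusted p = 0.0597, or 0.88 with an estimated correlation). In it 1 of 20 fell, ERD1, a chloroplast protease subunit, by 0.82 ± 0.215.

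Of 24 flavonoid genes 23 lay below 0 in the lines at 4 °C, 2 fell and 3 adjusted over the list alone. The glycosyltransferase UGT78D2 fell by 0.63 ± 0.141 (0.0409) and the phenylpropanoid hydroxylase C4H by 0.70 ± 0.199 (0.0495). Of 20 sugar genes 6 fell and 1 rose, 9 and 2 adjusted over the list alone. A score of nitrate-induced genes, chosen after seeing the data, was 1.466 in WT replicate 1 and -1.779 and -1.77 in WT replicates 2 and 3, 1.232, 1.338 and -1.306 in OE1, and 1.742, 1.738 and 1.492 in OE2. With WT replicate 1 and OE1 replicate 3 left out, the flavonoid list had a median of -0.984 (adjusted p = 0.00137) and the sugar list one of -0.895 and was not called (0.115). Without the 3 plants of low nitrate score, WT replicates 2 and 3 and OE1 replicate 3, the medians against the 1 WT plant left were -0.078 (0.731) and -0.137 (0.185), while with the nitrate score as a covariate both lists were called, at -0.364 (0.00052) and -0.249 (0.00267). Over all alternatives the adjusted p of the flavonoid list ran from 7.07e-07 to 0.731 and that of the sugar list from 0.00267 to 0.373, with 0.0692 without WT replicate 1 (median -0.852) and 0.0538 without OE2 replicate 2 for the latter.

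The other lists were not called in the lines at 4 °C, and single members passed. In ABA metabolism and signalling (median -0.312, adjusted p = 0.0996) 2 rose and 3 fell, 5 and 8 adjusted over the list alone. ABI3, a seed regulator of ABA responses, rose by 0.82 ± 0.182 and the ABA receptor PYL9 fell by 0.82 ± 0.192. The bZIP factors (median -0.244, 0.0666) had ABF3, an ABA-responsive factor, fall by 1.15 ± 0.318 and BZIP10 by 1.01 ± 0.285. The photosynthesis list (-0.032, 0.678) had LHCB4.3 and LHCA2, antenna proteins, fall by 0.70 ± 0.18 and 0.59 ± 0.164. Against WT replicate 1 alone, with OE1 replicate 3 also left out, this list had a median of -0.377, and of -0.421 in the interaction, differences that rest on 1 WT plant. The clock photoreceptor ZTL fell by 0.62 ± 0.129, the jasmonate-conjugating enzyme JAR1 by 1.02 ± 0.252 and the defence glucanase PR2 by 1.67 ± 0.462 (0.0493). Against WT replicate 1 alone, with OE1 replicate 3 also left out, PR2 differed by 0.03. The chaperone BIP2 rose by 0.53 ± 0.158, and in the senescence list (-0.507, 0.279) WRKY53 and DIN10 rose by 1.68 ± 0.364 (0.0408) and 3.49 ± 0.814 (0.0443). The root marker PRP3 was at least 1.4-fold higher (0.0119), above background in 3 of 6 line plants. The jasmonate list had a median of 0.208, or 0.036 with a dim member at 0, and a test toward lower values (0.872), and the heat shock list a median of 0.309, or 0 with dim members at 0 or their bound. The medians of the salicylic acid and flower lists were -0.371 (0.0607) and -0.324, and that of the root list 0.302 (0.0607). FT at -0.37, EPF2 at 1.12 (0.054), SUC2 at -0.27 and ATML1 at 0.31 did not pass.

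limma called 2153 genes in both lines against WT at 4 °C, 1292 higher and 861 lower (60% higher), against 1546 and 1560 (49.8%) after quantile normalisation and 1937 and 1973 (49.5%) after background correction with quantile normalisation. The count rested on which WT plants were used. It was 10934 without WT replicate 1, 5 without WT replicate 2 and 157 without WT replicate 3, and 62, 52 and 4982 without OE1 replicates 1, 2 and 3. It was 79, 72 and 76 without OE2 replicates 1, 2 and 3. Leaving out a 22 °C array, which enters only through the shared variance, gave 218, 203 and 93 (WT replicates 1, 2 and 3), 258, 119 and 143 (OE1) and 174 for either OE2 array. Without WT replicate 1 and OE1 replicate 3 it was 11437, 5842 higher and 5595 lower, and without WT replicates 2 and 3 and OE1 replicate 3, against 1 WT plant, it was 16, 15 higher and 1 lower. None of the 33 named calls held with each array left out: without WT replicate 2, 0 were kept, with adjusted p from 0.0833 (EXPB6, CIPK16 and ISA3) to 0.312 (CBF3). All 33 were kept without WT replicate 1 or OE1 replicate 3, 9 without WT replicate 3, 8 without OE1 replicate 1 or 2, and 8, 9 and 10 without OE2 replicates 1, 2 and 3. Without a 22 °C array 9 to 13 were kept. With WT replicate 1 left out ISA3 had 1.59e-06, CBF3 0.0026 (-1.40) and COR413IM1 4.76e-05 (-1.35), and over all alternatives these ran from 6.47e-07 to 0.218, 0.0026 to 0.947 and 4.76e-05 to 0.805.

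Line by line at 4 °C, the flavonoid list fell in OE1 (-0.525, adjusted p = 0.00145, or 0.572 with an estimated correlation) and in OE2 (-0.843, adjusted p = 5.53e-05, or 0.737 with an estimated correlation). The sugar list fell in OE1 (-0.739, adjusted p = 0.0132, or 0.251 with an estimated correlation), and the salicylic acid list fell in OE2 (-0.862, adjusted p = 0.00424, or 0.988 with an estimated correlation). limma called 690 genes in OE1, 512 higher and 178 lower, and 1117 in OE2, 548 higher and 569 lower. Of these 120 were shared in direction, 88 higher, with CIPK16, CLPB2, OLEO1 and EXPB6 among the largest, and 32 lower, with ISA3, UGE5, DPE2 and EXPB1 among the largest, and 3 were opposite. Independent lists would share 13.3 higher and 4.80 lower, and the simulations of unchanged groups gave a median and a highest value of 0. Splits of the same arrays gave up to 5916, so neither reference holds the structure of these arrays, and chance was not excluded. The covariance was 0.286 against 0.061 in the simulations (-0.013 to 0.255), and the correlation 0.692 against 0.553. Part of the excess may come from the common WT plants, which were not split. Pairs of fold changes that share no controls, a line at 22 °C against the other line at 4 °C, correlated across genes at 0.064 and 0.098.

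The higher share for OE1 at 4 °C was 74.2%, against 59% (396 and 275) after quantile normalisation, 56.4% (836 and 646) after background correction and 58.3% (360 and 257) in the authors' table. That of the shared calls was 73.3%, against 58.4% (80 and 57), 53.8% (189 and 162) and 58.8% (67 and 47). On the slide that held OE1 and a single WT plant at 4 °C, replicate 3, the block left 0 genes called for OE1 by limma, with 7128 at an unadjusted p under the threshold. Left-out arrays moved the count for OE1 to 10135, 17 and 381 (WT replicates 1 to 3), 48, 13 and 102 (OE1), 312, 240 and 252 (OE2) and 271 to 419 (each 22 °C array). They moved that for OE2 to 10191, 17 and 125 (WT), 445 and 2674 (OE1 replicates 1 and 3), 23, 46 and 100 (OE2) and 292 to 506 (each 22 °C array). The shared count moved to 7653, 2 and 60 (WT), 15, 7 and 54 (OE1), 11, 10 and 15 (OE2) and 46 to 75 (each 22 °C array). Without WT replicate 1 and OE1 replicate 3 these 3 counts were 10682, 10509 and 8536.

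Whether the cold response differs between the lines and WT was tested as an interaction. Each of the 7 named genes was at background in at least 1 whole group, so sizes are bounds, with n = 6 and 5 line plants and 3 and 3 WT plants. The response of MYB21 was at least 105.3-fold higher in the lines (adjusted p = 0.0169), that of the pectin methylesterase gene ATPMEPCRD at least 6.2-fold (0.0169), that of CRP4 at least 3.4-fold (0.0169) and that of the root marker PRP3 at least 2-fold (0.0227). CEP2 (0.0203), GH9B15 (0.00315) and ORA47 (0.00195) passed, but OE2 at 4 °C, and for GH9B15 and ORA47 both lines, were at background there, so no size is given. GH9B15 was above background in WT at 22 °C alone, and ORA47 there and in 1 OE1 plant at 22 °C, so these calls measure the loss in WT. For MYB21, most of the fitted difference of 7.4 was the gap already fitted at 22 °C, where the lines lay at -6.23 against WT. For ATPMEPCRD, both OE2 plants at 22 °C were at background and no OE1 or WT plant was. Its bound is a mean of the lines and does not show a difference in OE1. For the cold genes no difference passed: CBF1 (0.716, at background in WT at 22 °C), CBF2 1.07 (0.382), CBF3 -0.11 ± 0.446 (0.898), COR15A -0.04 ± 0.416 (0.966), COR15B 0.96 (0.245), RD29A -0.05 (0.94) and KIN1 0.77 (0.266).

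As lists, cold regulators differed in response by a median of 0.726 (adjusted p = 0.000208, or 0.455 with an estimated correlation), and adjusted over the list alone 8 of 22 were higher in the lines. Jasmonate genes differed by 0.861 (adjusted p = 0.000208, or 0.455 with an estimated correlation), and adjusted over the list alone 7 of 29 were higher. Against WT these 2 lists lay at -0.549 and -0.62 at 22 °C and at 0.176 and 0.208, not called, at 4 °C, so most of the gap lay at 22 °C. Flavonoid genes differed by -0.683 (adjusted p = 6.97e-05, or 0.455 with an estimated correlation), and adjusted over the list alone 3 of 24 were lower. Over all genes 0 members of these 3 lists passed in limma, and 3589 genes had an unadjusted p under the threshold. MYB15 at 2.38 (0.128), the ABA-degrading enzyme CYP707A3 at 2.47 (0.076), NAC055 at 2.00 (0.0638) and DIN10 at 4.68 (0.119) did not pass. The lists of ABA metabolism (median -0.016, mean 0.343), ABA- and drought-responsive genes (-0.299, mean 0.181) and bZIP factors (-0.066, mean 0.108) had median and mean of opposite sign, and none was called. With the nitrate covariate the first 2 were called, at 0.237 (0.00477) and 0.352 (0.0186).

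limma called 29 genes in the interaction, all higher in the lines' response (100%), against 22 higher and 6 lower (78.6%) after quantile normalisation, 19 and 5 (79.2%) after background correction and 21 and 5 (80.8%) in the authors' table. For OE1 alone it called 15 genes, 14 higher, and for OE2 alone 327, 224 higher and 103 lower. The count moved to 52 and 54 without WT replicates 1 and 2 at 22 °C, to 95 and 96 without OE1 replicates 1 and 3 at 22 °C, and to 12 and 68 without OE2 replicates 1 and 2 at 22 °C. It moved to 7525, 7 and 58 without WT replicates 1, 2 and 3 at 4 °C and to 44 without OE1 replicate 3 at 4 °C. Without WT replicate 1 and OE1 replicate 3 at 4 °C it was 8701. GH9B15 and ORA47 held with each array left out, while the other 5 named calls were lost without OE2 replicate 1 at 22 °C (adjusted p from 0.0521 to 0.074). Those of MYB21, CRP4, CEP2 and PRP3 were also lost without WT replicate 2 at 4 °C (0.0559 to 0.0859), and CEP2 and PRP3 without WT replicate 3 at 22 °C (0.0565 and 0.0601). Over all alternatives MYB21 ran from 9.52e-06 to 0.0559 and PRP3 from 0.00121 to 0.229. The lists of cold regulators (median 0.748, adjusted p = 0.079) and jasmonate genes (0.93, 0.128) lost their calls without WT replicate 1 at 4 °C, at medians no smaller than those above, with 7.34e-06 to 0.455 and 1.43e-06 to 0.455 over all. The flavonoid list kept its call without that plant (-1.042, 0.000151) and with the nitrate covariate (-0.371, 0.00331), and lost it without the 3 plants of low nitrate score (-0.21, 0.619), against 1 WT plant.

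The lines also differed from each other at 22 °C (n = 3 against 2). ATPMEPCRD (AT2G43050) was at least 109.5-fold higher in OE1 than in OE2 (adjusted p = 9.03e-07), where no plant was above background, while all 3 WT plants were. The zinc finger gene MIF2 (AT3G28917) was higher in OE1 by 5.04 ± 0.612 (0.00181, 1 of 2 OE2 plants at background), the stress factor RAP2.6 (AT1G43160) at least 11.7-fold (0.0446), and AtMYB103 (AT1G63910), a regulator of cell wall development, at least 11.1-fold (0.0156). The phenylpropanoid ligase 4CL3 was lower by 1.34 ± 0.271 on the log2 scale (0.0388), the acyltransferase GPAT3 by 1.1 ± 0.21 (0.0281), EGY3 by 1.04 ± 0.203 (0.0329) and GLYI8 by 0.72 ± 0.151 (0.0465). The salicylic acid list was higher in OE1 (0.871, adjusted p = 3e-06, adjusted p = 0.479 with an estimated correlation). limma called 187 genes, 175 higher in OE1 and 12 lower. The count moved to 111 without OE1 replicate 2, to 51 and 62 without OE2 replicates 1 and 2, and to 281 without WT replicate 1 at 4 °C. It was 344 without WT replicate 1 and OE1 replicate 3 at 4 °C. ATPMEPCRD and MIF2 held with each array left out. Of the 8 named calls, 5, 3 and 3 were kept without OE1 replicates 1, 2 and 3, 2 without either OE2 array, all without WT replicate 1 at 4 °C, and 4 to 7 without any other array. Without OE2 replicate 1 the adjusted p was 0.177 for AtMYB103, 0.34 for GPAT3, 0.24 for RAP2.6, 0.301 for 4CL3, 0.257 for EGY3 and 0.268 for GLYI8, and over all alternatives AtMYB103 ran from 0.00189 to 0.236.

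At 4 °C (n = 3 against 3) the peptide gene RTFL15 (AT1G68825) was at least 3.6-fold higher in OE1 than in OE2 (adjusted p = 0.000362). The cytochromes CYP71B9 and CYP81D7 were at least 4.6- and 1.7-fold higher (0.0283 and 0.0396) and the haem oxygenase HO4 at least 2.6-fold. PHI-1 (AT1G35140), a phosphate-responsive protein, was lower by 3.28 ± 0.686 on the log2 scale (0.0262), CYP94C1, which breaks down active jasmonate, by 2.24 ± 0.468 (0.0284), PUP18 by 2.2 ± 0.48 (0.0305, 1 of 3 OE1 plants at background), and ARI16 at least 1.3-fold. The photosynthesis list was higher in OE1 (0.42, adjusted p = 1.64e-06, adjusted p = 0.763 with an estimated correlation), as was the salicylic acid list (1.023, adjusted p = 0.00363, adjusted p = 0.763 with an estimated correlation). limma called 641 genes, 454 higher and 187 lower (70.8% higher, against 58.7% from 622 and 437 after background correction and 60.7% from 378 and 245 in the authors' table). The count moved to 418 without OE1 replicate 2 at 22 °C, to 2235 without WT replicate 1 at 4 °C, to 384, 362 and 85 without OE1 replicates 1, 2 and 3, and to 134, 134 and 211 without OE2 replicates 1, 2 and 3. It was 878 without WT replicate 1 and OE1 replicate 3, and 999 without WT replicates 2 and 3 and OE1 replicate 3. RTFL15 was the 1 of 8 named calls that held with each array left out, with 3, 3 and 2 kept without OE1 replicates 1, 2 and 3, 1, 2 and 4 without those of OE2, and 7 or 8 without any other array. The adjusted p of PHI-1 ran from 0.00898 to 0.0988 over all alternatives.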

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

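The tests on WT replicate 1 at 4 °C, on floral tissue and on nitrate state were chosen only after the results were seen, while the slide test at 22 °C and the counts of other splits were set before.

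The response to cold differed between the lines and WT in a test of the difference itself, which called 29 genes for both lines, 15 for OE1 and 327 for OE2. The fitted differences, which are no sizes of change because each gene was at background in at least 1 whole group, were 7.40 for MYB21, 5.59 for CEP2, 4.73 for GH9B15, 3.77 for ORA47, 2.82 for ATPMEPCRD, 2.75 for CRP4 and 1.81 for PRP3 on the log2 scale. The bounds were at least 105.3-fold for MYB21, 6.2-fold for ATPMEPCRD, 3.4-fold for CRP4 and 2-fold for PRP3, with none for CEP2, GH9B15 and ORA47, which were at background in OE2 at 4 °C. Among lists the median difference was 0.73 for cold signalling regulators, -0.68 for flavonoid synthesis and 0.86 for jasmonate genes, none called with an estimated correlation (adjusted p = 0.455 for each), and the first and last not without WT replicate 1 at 4 °C (0.079 and 0.128). Of 100 splits of the arrays, 5 gave as many genes as the real 29, with a highest other of 3485, so chance was not excluded. For the 3 lists, 83 of 100 splits gave as many, with a median of 5 and a highest of 12 in the other splits, so chance was not excluded there either. The split with 3485 genes put WT replicates 2 and 3 and OE1 replicate 3 at 4 °C together, which points to a structure of the samples.

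WT replicate 1 at 4 °C stood apart from WT replicates 2 and 3 and beside most line plants, and OE1 replicate 3 leaned the other way. A slide effect was argued against, because the plant correlated at 0.948 with WT replicate 2 of its own slide and at 0.979 to 0.986 with the OE2 arrays of another slide. A difference in nitrate state between single plants is a candidate explanation: 15 nitrate-induced genes not looked at before were higher in WT replicate 1 than in the higher of WT replicates 2 and 3 by a mean of 1.852, above 100% of 10000 random lists matched on expression, whose highest was 1.01, and 12 of the 15 were higher in it than in both. A line plant carrying a WT label stays open, since on 565 genes that separate OE1 (1) from OE2 (0) the plant lay at 0.434, outside the OE1 plants (0.691 to 0.895) and the OE2 plants (0.002 to 0.369), each placed on genes chosen without it, and below WT replicates 2 and 3 (0.533 and 0.676). What set the nitrate state of the plants was not tested, and genotype, soil and harvest remain untested.

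The flower and jasmonate lists were lower in both lines than in WT at 22 °C, neither called with an estimated correlation (adjusted p = 0.342 and 0.0916), the flower list not lower with the slide as a block (0.136), while the pollen score, not tested between groups, was below all WT plants in OE2 and OE1 replicate 3 and within the WT range in OE1 replicates 1 and 2. Less floral tissue in some of the sampled line plants may account for the flower and pollen genes: the floral organ score varied by 2.035 between the 3 OE1 plants, against 0.345 between WT plants, and the pollen score by 4.883 against 1.477. With the floral score as a covariate in the 22 °C arrays the jasmonate median went from -0.62 to -0.832, or 1.341 of its size. Leaving out 1 array gave 1.007 (without WT replicate 3) to 1.682. The OE1 plants dominate this fit, so floral tissue was not excluded. An effect of the transgene on flowering or on jasmonate genes stays open and untested.

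For the genes lower in both lines at 22 °C a slide effect cannot be told apart from the genotype. On 169 such genes, chosen without it, OE1 replicate 1 on the WT slide lay at 0.358 between WT (0) and the other OE1 plants (1), with quartiles of 0.119 and 0.661, while single WT plants lay between -0.151 and 0.137. This value lies between those that a slide effect and a line effect would give, and OE1 replicate 1 was also the OE1 plant with the highest floral score (1.975).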

How the results depend on the processing

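The flower and nitrate covariates and the sets of 2 and 3 cold arrays left out were chosen only after the results were seen. The cold responses kept their counts within 1.5 times under each alternative except the 2-fold threshold, and the 24 called list tests and the 125 called named results kept their sign under each scaling, while 9 list tests and 5 named results that were not called changed sign under at least 1 scaling. The percentile over bright probes kept each count listed here within 1.5 times. Signal over background limits the genes near the floor: 27598 of 43603 probes were well above background on all arrays, and the strict filter left 65 of 69 list tests and 137 of 198 results for named genes. Of the results for named genes 57 lost their call with only the compared arrays, 41 of 197 without the 3 cold arrays, 37 with the nitrate covariate, 30 with the flower covariate and 29 with no filter, and 33 gained one with array weights. Of the list tests 24 lost their call with an estimated correlation, 5 with the flower covariate and 0 to 4 under each other camera alternative that kept all arrays or left out the 2 or 3. In what follows, comparisons are with WT unless stated, a value alone in parentheses is the reported one, a median with its adjusted p is the alternative's, and the cause was not tested unless given.

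Quantile normalisation gave 170 genes for both lines at 22 °C (111), 1902 for OE2 at 4 °C (1117) and a mean correlation of 0.117 between line effects that share no controls (0.081). The authors' table gave 167, 1772 and 0.117. Background correction with quantile normalisation gave 18 for OE1 at 22 °C (11), 1482 for OE1 at 4 °C (690), 2954 for OE2 and 3910 for both at 4 °C (2153), 1059 for OE1 against OE2 at 4 °C (641), 16 and 351 shared at 22 and 4 °C (10 and 120), and 0.16. No filter gave 356 for OE2 and 219 for both at 4 °C, 61 shared at 4 °C, 0.053, and a call of the ABA- and drought-responsive list at 4 °C (-0.433, adjusted p = 0.00768, against 0.0597). The strict filter, with fewer genes tested, gave 3, 168 and 59 for OE1, OE2 and both at 22 °C (11, 325 and 111), 2499 and 3668 for OE2 and both at 4 °C, 10 for the interaction (29), 120 for OE1 against OE2 at 22 °C (187), 3 shared at 22 °C, and 0.148. The mean of probes gave 46 for the interaction. The trended and robust variance gave 2345 and 3488 for OE2 and both at 4 °C and 184 shared.

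Array weights gave 58, 1568 and 630 for OE1, OE2 and both at 22 °C, 10402, 10368 and 11003 at 4 °C, 8492 for the interaction, 771 and 2370 for OE1 against OE2 at 22 and 4 °C, and 52 and 8055 shared. Only the compared arrays, with fewer samples to estimate the spread, gave 0 for OE1 at 22 °C in limma (1513 at an unadjusted p under the threshold), 146 for OE2, 10 for both, 0 for OE1 at 4 °C (2415 unadjusted), 6 for OE2, 41 for both, 6 for OE1 against OE2 at 22 °C, and 2 and 10 shared. The slide block gave 40 for OE2 and 11 for both at 22 °C and 0 for OE1 at 4 °C (7128 unadjusted), turned the flower list to 0.136 (-0.768) and the heat shock list to 0.41 (-0.229) in both lines at 22 °C, the latter called (adjusted p = 0.00111), values that pass through OE1 replicate 1 alone. The 2-fold threshold gave 6645, 7016 and 7195 for the cold responses of WT, OE1 and OE2, 325, 508 and 647 for OE1, OE2 and both at 4 °C, 317 for OE1 against OE2 at 4 °C, and 58 shared at 4 °C. With an estimated correlation 0 of 72 list tests in camera were called (24), 11 at an unadjusted p under the threshold, and fry, which asks whether a list moved at all, called 24.

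Pairing of plants by number is open: same-numbered deviations correlated at a median of 0.02 (-0.30 to 0.37), others at -0.03. Of 17 arrays 10 correlated best with their own number. The replicate block gave 2072 for OE2 at 4 °C, 58 for the interaction (51 higher and 7 lower), 0.055 for the correlation without shared controls, and a call of the ABA- and drought-responsive list at 4 °C (-0.433, adjusted p = 0.0439), and it moved 8 of the 198 results for named genes and 2 of the 69 list tests across the threshold.

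The flower covariate gave 5, 160 and 56 for OE1, OE2 and both at 22 °C, 273, 734 and 229 at 4 °C, 5 and 64 shared, -0.038, a call of the ABA- and drought-responsive list at 4 °C (-0.445, adjusted p = 0.0238), and a call of the photosynthesis list at 22 °C at -0.112 (0.019), adjusted p = 0.0414. It also called the salicylic acid list at 22 °C (-0.356, adjusted p = 0.0259) and 4 °C (-0.463, adjusted p = 0.0238) and the root list at 4 °C (0.319, adjusted p = 0.0252), while calls were lost by the clock (-0.062, adjusted p = 0.173) and flower lists (-0.116, 0.791) at 22 °C and, in the cold response of WT, by the flower (0.065, 0.692), cold regulator (0.506, 0.101) and ABA metabolism lists (-0.668, 0.0775). The nitrate covariate gave 634 and 178 for OE2 and both at 22 °C, 4 and 12 for OE2 and both at 4 °C, 1 shared at 4 °C, 15 for the interaction, 303 and 1434 for OE1 against OE2, and -0.009, with calls gained by the root list at 4 °C (0.405, adjusted p = 0.00683) and, in the interaction, by ABA metabolism (0.237, 0.00477), ABA- and drought-responsive (0.352, 0.0186, against -0.299), senescence (0.498, 0.00642) and root lists (0.353, 0.0109). Leaving out WT replicate 1 and OE1 replicate 3 at 4 °C gave 7, 938 and 184 for OE1, OE2 and both at 22 °C, 10682, 10509 and 11437 at 4 °C, 8701 for the interaction, 344 for OE1 against OE2 at 22 °C, 6 and 8536 shared, and 0.105. Leaving out WT replicates 2 and 3 and OE1 replicate 3 at 4 °C, with WT then 1 cold plant, gave 904 for OE2 at 22 °C, 43, 20 and 16 at 4 °C, 15 for the interaction, 999 for OE1 against OE2 at 4 °C, 8 shared at 4 °C, -0.121, a bZIP list difference of 0.215 in the interaction (-0.066), calls there of ABA metabolism (0.323, adjusted p = 0.000103), senescence (0.679, 0.000102), clock (0.277, 0.041) and flower lists (1.345, 0.0139), and PR2 at 0.032 in both lines at 4 °C.

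With each array left out in turn, most of the highest counts came without WT replicate 1 at 4 °C, except for OE1, both lines and shared calls at 22 °C (OE1 replicate 1 at 22 °C), and the lowest at 4 °C without WT replicate 2, except for OE1 against WT (OE1 replicate 2) and OE1 against OE2 (OE1 replicate 3). Counts ran from 10760 to 13232 for the cold response of WT, 11075 to 14072 for OE1 and 9393 to 13772 for OE2. At 22 °C they ran from 5 to 51 for OE1, 47 to 669 for OE2, 22 to 214 for both and 4 to 39 shared, and at 4 °C from 13 to 10135, 17 to 10191, 5 to 10934 and 2 to 7653. They ran from 7 to 7525 for the interaction and from 51 to 281 and 85 to 2235 for OE1 against OE2 at 22 and 4 °C. The list shifts at 4 °C ran from 0.034 to 0.302 for cold regulators, -0.043 to 0.114 for effectors and -0.561 to -0.325 for ABA- and drought-responsive genes. The last passed the threshold without OE1 replicate 3 at 22 °C, WT replicate 3, any OE1 plant or OE2 replicate 1 at 4 °C (adjusted p from 0.0135 to 0.0481). The correlation without shared controls ran from 0.025 to 0.117 and the number of list calls from 21 to 30.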

Other observations

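The counts of other splits were set before the data were examined, and the values per plant in this paragraph were chosen after and not tested. Single plants of a group differed in some gene lists. The mean log2 signal of the salicylic acid and defence list was -0.35 in OE1 replicate 3 at 22 °C and at most -1.37 in the other 7 plants. At 4 °C it was -1.46 to -1.88 in OE2 and -1.36 to -0.62 in WT. The mean of the heat shock list at 22 °C was 0.3 and 0.37 in OE1 replicates 2 and 3 and between 0.86 and 1.15 in the other 6 plants. The clock list was 0.46 to 0.82 in all 9 plants at 4 °C (0.47 in WT replicate 1). Mixing morning and evening genes, it cannot date harvest.

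Other splits of the arrays were counted for each comparison of at least 3 arrays against 3. For comparisons with 10 splits the splits are too few for a share under 0.05. In the cold response of WT 1 split, the real one, gave 12175 genes, with a highest other of 4. For lists 1 split gave 10, with a median of 6 and a highest of 9 in the other splits. For the cold response of OE1 it was 1 split with 12535 genes and a highest other of 1. For OE1 against WT at 22 °C 2 splits reached the real 11, with a highest other of 29 (OE1 replicate 3 with WT replicates 1 and 3). For OE1 against WT at 4 °C 2 reached the real 690, with a highest other of 7847 (WT replicate 1 with OE1 replicates 1 and 2), which points to the structure of the samples described for WT replicate 1. For OE2 against WT at 4 °C 1 split gave the real 1117 with a highest other of 7, and for OE1 against OE2 at 4 °C 1 gave the real 641 with a highest other of 0.

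Among 100 splits for both lines against WT at 22 °C 3 gave as many genes as the real 111, an unadjusted share under 0.05. The highest other was 164 (OE1 replicate 3 and both OE2 plants against the rest). For lists 28 gave as many as the real 9 (highest other 13), so chance was not excluded. At 4 °C 5 splits gave as many genes as the real 2153, with a highest other of 8614 (WT replicates 2 and 3 and OE1 replicate 3 against the rest), so chance was not excluded, and this split, which puts the 3 plants with nitrate scores from -1.779 to -1.306 together, points to a structure of the samples. For the lists called at 4 °C 97 splits gave as many as the real 2, with a highest other of 10. For calls shared by both lines at 4 °C 3 splits gave as many as the real 120, and the same split of the 3 plants gave 5916. The count was 2 without WT replicate 2, so chance was not excluded. The list shifts at 4 °C were reached by 44 splits for cold regulators (0.176, highest other 0.421), 92 for cold-regulated effectors (0.02, highest other 0.276) and 7 for ABA- and drought-responsive genes (size 0.433, highest other 0.561), so chance was not excluded for any of them.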
